A study of Homo sapiens with 12 samples.

How the data were processed

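K562 is an established human leukemia cell line that carries erythroid, megakaryocyte and myeloid features. RNA was sequenced from 6 K562 lines, 2 wild type (WT) and 4 with mutated DNMT3A, each as 1 library in each of 2 sets. The column names of the authors' deposited gene tables call the WT lines WTO (replicate 1) and WT9 (replicate 8) and the mutant lines KO5, KO12, KO17 and KO27 (replicates 3, 4, 5 and 6). The labels state that RNA was taken in the logarithmic and the plateau stage of growth. They do not state the stage of each library; the deposited table of the first set is named logarithmic and that of the second set plateau. The labels call the libraries paired-end TruSeq libraries from total RNA, sequenced on an Illumina HiSeq instrument.

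The deposited gene tables hold raw read counts for 14822 genes in 6 libraries each. Per the labels, reads were aligned to hg19 with TopHat2 and counted with featureCounts; versions, settings and the gene annotation are not given in the sources used here. The same deposited tables hold FPKM values from Cufflinks for all 12 libraries, identical in both tables, and these were used only for a check of the unit. The authors' deposited tables also hold a log2 fold change of mutant over WT, a log2 mean CPM, a p-value and an FDR for each gene, made with edgeR per the labels; which edgeR test was used is not stated. The deposited tables list genes left by a filter on FPKM that is named in the table names only.

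Splicing was deposited as 16 tables from MISO, 6 that compare the libraries of 1 line between the sets for skipped exons, and 10 that compare a WT sample with a mutant sample within a set for 5 event types. Per the file headers, each event has a fraction (percent spliced in, the posterior mean for the first isoform listed) in each of the compared samples, bounds of its credible interval, the difference of the fractions, a Bayes factor (a ratio of the evidence for and against a difference), and read counts per isoform class as text. Only events past a filter are listed; every listed event had a Bayes factor of at least 10 and an absolute difference of at least 0.2, and the rule itself is not stated. The WT and mutant samples of the genotype tables are called pools here, since which libraries each holds is not stated. The deposited table of skipped exons by genotype in the first set held 234 lines for 117 events, each listed more than once, and every event was counted once. Reads unique to an isoform were used to check which isoform the fraction refers to, and in 488 of 494 events with such reads in both samples the fraction moved with the longer isoform or the first of a pair of exclusive exons. Coordinates were matched to GENCODE v44 gene models lifted to GRCh37, the same assembly as hg19; the 23 chromosome names in the tables were all found there, 496 of 496 events lay in a gene, and 305 of 323 skipped exons had the same start and end as an annotated exon.

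Counts were analysed with edgeR 4.0.16 in R 4.3.3. TMM factors and filterByExpr were applied to the libraries of each comparison, a quasi-likelihood model was fitted, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Genotype was tested in the first set, in the second set, and over both sets with the counts of each line summed, so that the line was the replicate. The difference of the genotype effect between the sets, and the difference between the sets in mutant lines and in WT lines, were tested with the line as a block. DESeq2 1.42.0 was run on the same genes. The p-values of gene tests measure only the spread between these lines and libraries. Those of the list test camera (below) set members against other genes, so that genes act as replicates apart from the correlation assumed between them. Those of splicing events within a table treat events as independent. Levels are counts scaled to library size (CPM) with TMM factors of the libraries compared, given as the mean and SD; fold changes are log2 values of the fitted model with their SE. Where a group held 0 counts, the fold is a lower bound computed with 3 counts over the group. Intervals and such floors cover counting error only.

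Gene lists were tested with camera from limma 3.58.1 at a correlation between genes of 0.01, two-sided and adjusted over 18 lists, with the correlation estimated per list as an alternative and with fry beside it. The lists held 633 symbols, of which 544 were in the tables. They covered DNA methylation machinery, splicing factors, DNA damage and repair, p53 targets and growth arrest, proliferation and mitosis, the erythroid program, megakaryocyte markers, myeloid and monocyte markers, lymphoid markers, epithelial, fibroblast and endothelial markers, stem cell and HOX genes, cancer-testis genes, interferon response, amino acid and ER stress response, glycolysis and hypoxia, cholesterol biosynthesis, cytosolic ribosomal proteins, and replication-dependent histones. Within each list, members were also tested with p-values adjusted over the list alone. The comparisons, tests, lists, naming rule and most alternatives were fixed before the data were examined.

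Genes were named by rule. DNMT3A came first; then up to 10 rising and 10 falling genes with the largest fold change among those past the threshold, with the groups apart or every pair moving the same way and a mean of at least 1 CPM; where fewer than 5 passed in a direction, the 5 with the smallest p in that direction were named as values that did not pass. From each list up to 4 members with the smallest p were taken, and from the authors' deposited tables up to 5 genes in each direction at an FDR under 0.05. Splicing events were named when both genotype comparisons listed them, or as the 2 largest differences per event type and set; events listed in at least 3 mutant lines and no WT line, or in both WT lines and no mutant line, would also have been named, and there were 0 of either. Any other named feature is marked as chosen after its values were seen.

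The share of skipped-exon events with higher inclusion was tested with an exact two-sided binomial test and an exact 95% interval (Clopper-Pearson), and line counts with an exact two-sided permutation test over 15 arrangements of 2 WT and 4 mutant lines (Python 3.11.15, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3). Figures were drawn with matplotlib 3.10.9. Alternatives were DESeq2 size factors, no filter on low counts, DESeq2, no block, all 12 libraries in the fit, the line as a random effect in limma, each library or line left out in turn, stricter Bayes factor, difference and read minimums, and matching events by overlap. Added after the data were seen were an edgeR exact test without a filter, an exchange or removal of lines KO5 and KO12, counting every line of the splicing tables, and leaving out events that lack the reads of an isoform in 1 pool.

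The pipeline was tested on simulated data made from these counts. For genotype in the first set, 44.8% of genes changed 2-fold and 92.4% of genes changed 8-fold were recovered, with 12 false calls. For genotype over both sets the shares were 43.3% and 93.9%, with 8 false calls. For the WT lines between the sets they were 91% and 100%, with 24 false calls. Each gene was drawn independently from a common mean for all libraries, so shifts that genes share within a line were absent. The shares therefore do not tell how many changes of that size the real comparisons could miss. Library totals ranged from 10789791 to 19232729 counts. Reads themselves were not analysed here, so the DNMT3A mutations could not be read.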

Results

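Gene expression and splicing were measured by RNA sequencing in 6 K562 lines, 2 WT and 4 with mutated DNMT3A, a gene that encodes a de novo DNA methyltransferase. Each line gave 1 library in the first set and 1 in the second set, so that each set held 2 WT and 4 mutant libraries. Total counts ranged from 10789791 to 19232729 per library, and the 10 most abundant genes took 6.36% to 8.51% of them. The title of the series names abnormal splicing and genomic instability after DNMT3A mutation, and the comparison of genotypes addresses these in the transcriptome.

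The DNMT3A transcript was present in every mutant library. In the first set its counts were 113 and 99 in the WT lines WTO and WT9, and 95, 50, 63 and 117 in the mutant lines KO5, KO12, KO17 and KO27. In the second set they were 105 and 110 in the WT lines, and 92, 96, 52 and 110 in the mutant lines in the same order. The mean level was 5.91 ± 0.0932 CPM (SD, n = 2) in WT and 5.68 ± 1.44 (n = 4) in mutant libraries of the first set, and 6.20 ± 0.187 against 6.29 ± 1.18 in the second set. The log2 fold change of DNMT3A was -0.06 ± 0.30 (SE) and 0.02 ± 0.26, smaller than its SE in either set. The mRNA level does not check a coding mutation.

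In the first set, SLIT2, ROBO2 and EVC, expressed in WT lines and at or near 0 in mutant lines, were among the genes with the smallest p of the genotype comparison. SLIT2, a secreted guidance ligand, stood at 27.7 ± 12.1 CPM (SD, n = 2) in WT and 0.186 ± 0.268 (n = 4) in mutant libraries, a log2 fold change of -7.03 ± 0.90 (SE). ROBO2, a receptor for SLIT ligands, stood at 4.98 ± 3.36 CPM in WT and had 0 counts in all 4 mutant libraries, at least 96.2-fold lower. EVC, a ciliary protein of Hedgehog signalling, differed by a log2 fold change of -4.01 ± 0.85, and FYB, an adaptor protein of blood cells, stood at 34.1 ± 14.7 CPM in WT and 8.56 ± 2.72 in mutant libraries. LRMP, a membrane protein of lymphoid cells, had -2.94 ± 0.63. ITGA4, an integrin subunit of blood cell adhesion, had 248 counts in WT9, 13 in WTO and 0 in the mutant lines. SEMA3D, a semaphorin, had 77 counts in WT9, 2 in WTO and 1 in the 4 mutant libraries together. A single WT line thus carried most of the level of ITGA4 and SEMA3D. LIN28A, an RNA-binding repressor of let-7 maturation, was 41.0 ± 40.8 CPM in WT and 5.64 ± 4.91 in mutant libraries.

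Higher in the mutant libraries of the first set were BTN2A2, a butyrophilin, with 8.06 ± 0.953 CPM in WT (SD, n = 2) and 17.1 ± 1.28 in mutant (n = 4) libraries, and WDR26, with a log2 fold change of 0.52 ± 0.10 (SE). The immediate early gene EGR3 had 3.96 ± 0.81, at 0.0824 CPM in WT and 1.42 in mutant libraries. Small RNA genes were among them, with 2.58 ± 0.53 for the microRNA gene MIR3189 and 1.56 ± 0.35 for SCARNA5, a Cajal body RNA. Whether the reads at MIR3189 came from the microRNA or from a longer transcript over the same site was not tested. Scaled over all 12 libraries, SCARNA5 stood at 12.5 CPM in WT and 36.7 in mutant libraries of the first set. In the second set it stood at 37.0 and 45.8. A lower recovery of short RNA in the WT libraries of the first set is left open for such genes in the closing section. GDF15, a stress-responsive cytokine, stood at 14.4 ± 5.63 CPM in WT and 75.0 ± 38.1 in mutant libraries, and NEAT1, the scaffold RNA of paraspeckles, at 60.3 ± 5.14 and 146 ± 49.2.

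No gene passed the edgeR test in the first set. Of 13478 genes, 0 had an adjusted p under 0.05 (smallest adjusted p = 0.781), 574 had an unadjusted p under 0.05, and DESeq2 called 10. Of these 10, 6 were higher and 4 lower in mutant lines. DESeq2 adjusted p-values were 0.0189 for SLIT2, 1.88e-05 for ROBO2, 0.026 for EVC, 0.00161 for FYB, 0.000648 for BTN2A2, 0.0243 for WDR26, and 0.0189 for SCARNA5 and GDF15. An edgeR exact test without a filter, chosen after the data were seen, called 5 genes, all lower in mutant lines, namely ROBO2, SLIT2, ITGA4, FYB and EVC. The authors' deposited table listed 10 genes at an FDR under 0.05. Of these, the authors' values were lower in mutant lines for 7, with log2 fold changes of -9.89 for ITGA4, -9.27 for ROBO2, -7.05 for SLIT2, -6.45 for SEMA3D, -4.03 for EVC, -2.01 for FYB and -1.13 for GAGE1. The authors' deposited table listed 3 as higher, GDF15 with 2.37, NEAT1 with 1.27 and the small nucleolar RNA SNORD17 with 1.04.

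**Figure D1:**
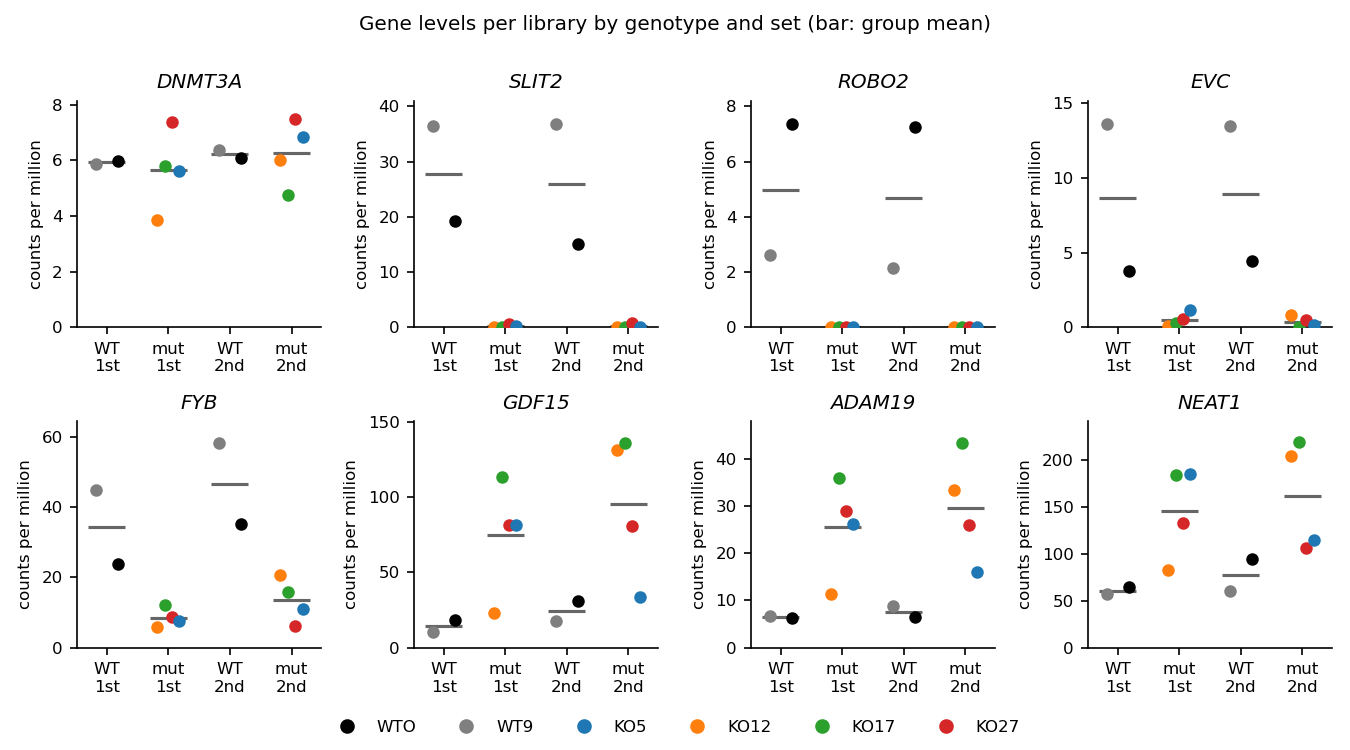
Levels in CPM (vertical axis) of 8 genes in each library, by genotype and set; points are libraries coloured by line label and bars are group means. SLIT2 and ROBO2 were near or at 0 in all mutant libraries, while DNMT3A stood between 3.87 and 7.49 CPM in every library.

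Several gene groups lay to 1 side of all other genes in the first set although no member passed over all genes tested. Splicing factors were lower in mutant lines, with negative log2 fold changes in 52 of 70 measured members. SRSF2 stood at -0.45 ± 0.17 (SE), SNRPB at -0.23 ± 0.10 and CLK2 at -0.26 ± 0.12, while the splicing coactivator SRRM2 had 0.30 ± 0.092. The list had a camera adjusted p of 0.00289, and adjusted p = 0.782 with an estimated correlation. Replication-dependent histones were negative in 16 of 17 members (HIST1H2AC -0.39 ± 0.14, HIST1H1E -0.35 ± 0.16; adjusted p = 0.000274, and adjusted p = 0.782 with an estimated correlation). Cytosolic ribosomal proteins were negative in 37 of 46 (RPS15 -0.15 ± 0.083; adjusted p = 0.0306, and adjusted p = 0.879 with an estimated correlation). The erythroid program was positive in 38 of 47 members. The embryonic globin HBZ stood at 1.93 ± 0.77 and the erythroid nuclear protein HEMGN at 1.04 ± 0.38 (adjusted p = 0.00289, and adjusted p = 0.782 with an estimated correlation). Megakaryocyte markers were positive in 8 of 9. The platelet integrin ITGB3 stood at 2.29 ± 0.76 and the matrix protein THBS1 at 3.79 ± 1.74 (adjusted p = 0.00817, and adjusted p = 0.782 with an estimated correlation). Amino acid and ER stress genes were positive in 26 of 31. The transcription factor ATF3 stood at 1.13 ± 0.50 and ATF4 at 0.29 ± 0.14 (adjusted p = 0.00636, and adjusted p = 0.782 with an estimated correlation).

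The other 12 lists did not pass in the first set. DNA damage and repair genes were positive in 34 of 70 members (POLQ 0.26 ± 0.13; camera adjusted p = 0.725). The share was 16 of 21 for p53 targets (BBC3 1.01 ± 0.35; adjusted p = 0.118) and 7 of 18 for DNA methylation machinery (TDG -0.21 ± 0.11; adjusted p = 0.447). Proliferation genes were positive in 21 of 44 (MKI67 0.30 ± 0.10; adjusted p = 0.573), myeloid markers in 8 of 11 (adjusted p = 0.132) and interferon genes in 21 of 25 (adjusted p = 0.514). Glycolysis and hypoxia genes had an adjusted p of 0.614 and cholesterol genes of 0.911. Among markers of other cell types, lymphoid markers were positive in 6 of 7 (adjusted p = 0.447) and epithelial, fibroblast and endothelial markers in 5 of 10 (adjusted p = 0.911). Stem cell and HOX genes had a median of 0.085, a mean of 0.38 and a downward test (adjusted p = 0.786). Cancer-testis genes had a median of 0.063, a mean of 0.20 and a downward test (adjusted p = 0.447). The test for glycolysis was also downward against a median of 0.0022 and a mean of 0.081. Adjusted over the list alone, 0 members of any list passed, and by fry 0 lists passed. Without KO5 or without WT9, 3 lists passed instead of 6.

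In the second set SLIT2, ROBO2 and EVC were again among the genes with the smallest p. SLIT2 stood at 25.9 ± 15.3 CPM in WT (SD, n = 2) and 0.222 ± 0.353 in mutant libraries (n = 4). ROBO2 stood at 4.68 ± 3.6 in WT and 0 counts in all mutant libraries, at least 85.5-fold lower. EVC had a log2 fold change of -4.53 ± 0.94 (SE). ITGA4 had 248 counts in WT9, 15 in WTO and 1 in the mutant libraries together. GAGE1, a cancer-testis gene whose reads paralogs may share, stood at 83.4 ± 16.9 CPM in WT and 42.7 ± 4.22 in mutant libraries. Higher in mutant libraries were SAT1, an acetyltransferase of polyamine catabolism, with 23.0 ± 3.08 and 49.0 ± 8.82 CPM, and ECM1, a matrix protein, with 26.5 ± 0.845 and 51.7 ± 9.73. FAM122C also stood higher, with a log2 fold change of 1.07 ± 0.21, the zinc finger gene ZNF626 with 1.24 ± 0.25, and LRGUK with 3.36 ± 0.68. ADAM19, a membrane metalloprotease, had 7.58 ± 1.73 and 29.8 ± 11.7 CPM, and GDF15 24.1 ± 9.40 and 95.7 ± 48.6.

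By edgeR 0 of 13533 genes passed in the second set (smallest adjusted p = 0.737), with 693 genes at an unadjusted p under 0.05. DESeq2 called 17, of which 12 were higher in mutant lines. DESeq2 adjusted p-values were 5.84e-08 for SLIT2, 0.0001 for ROBO2, 0.0133 for EVC, 0.000759 for ITGA4 and GAGE1, 0.00344 for SAT1, 0.0186 for ECM1, 0.0181 for FAM122C and ZNF626, and 0.00434 for ADAM19. The edgeR exact test without a filter called 5 genes, all lower, namely ROBO2, SLIT2, ITGA4, GAGE1 and EVC. The authors' deposited table listed 9 genes at an FDR under 0.05, of which 7 were also listed in the first set. LIN28A at -3.00 and ADAM19 at 1.96 (log2) were the additions. Across 13262 genes tested in both sets the genotype log2 fold changes of the sets correlated with r = 0.90. Genes are not independent replicates, and the sets share their lines.

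In the second set 57 of 70 splicing factors were negative. PRPF31, a spliceosome component, stood at -0.37 ± 0.11 (SE), SRSF2 at -0.45 ± 0.14 and SNRPG at -0.41 ± 0.16 (camera adjusted p = 1.55e-06, and adjusted p = 0.648 with an estimated correlation). Histones were negative in 16 of 17 members (HIST2H2BE -0.34 ± 0.14; adjusted p = 1.55e-06, and adjusted p = 0.648 with an estimated correlation). Ribosomal proteins were negative in 42 of 46 (RPL34 -0.29 ± 0.12; adjusted p = 0.00376, and adjusted p = 0.648 with an estimated correlation). Positive were p53 targets in 15 of 21. The apoptosis-related TP53INP1 stood at 1.22 ± 0.34 and the repair gene DDB2 at 0.55 ± 0.20 (adjusted p = 0.0435, and adjusted p = 0.648 with an estimated correlation). The erythroid program was positive in 35 of 46, with the carbonic anhydrase CA2 at 6.35 ± 2.33 (adjusted p = 0.0388, and adjusted p = 0.648 with an estimated correlation). Myeloid markers were positive in 10 of 13, with the integrin ITGAX at 1.76 ± 0.65 and the receptor CSF3R at 1.61 ± 0.61 (adjusted p = 0.0388, and adjusted p = 0.648 with an estimated correlation). Adjusted p-values of the other 12 lists ran from 0.0555 for amino acid and ER stress genes to 0.858, and 0 lists passed by fry. Cancer-testis genes had a median of 0.031 and a mean of 0.14 with a downward test. The test was also downward for stem cell and HOX genes, with a median of -0.079 and a mean of 0.10, and for glycolysis genes, with a median of -0.037 and a mean of 0.033. Adjusted over the list alone, 1 member passed, GAGE1, which was lower, and over all genes 0. Without KO12, 2 lists passed, and without WT9, or with no filter on low counts, 3.

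The library labels of the lines KO5 and KO12 bear on every comparison that joins the sets. Across genes, log2 CPM of the first set library of KO5 correlated with the second set library of KO12 at r = 0.9891, and that of KO12 with the second set library of KO5 at 0.9902. With their own labels the correlations were 0.9595 for KO5 and 0.9541 for KO12, whereas the other 4 lines had 0.9894 to 0.9941. Comparisons over both sets are therefore also given with these labels exchanged in the second set and without these lines, alternatives chosen after the data were seen; comparisons within a set do not use the pairing.

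**Figure D2:**
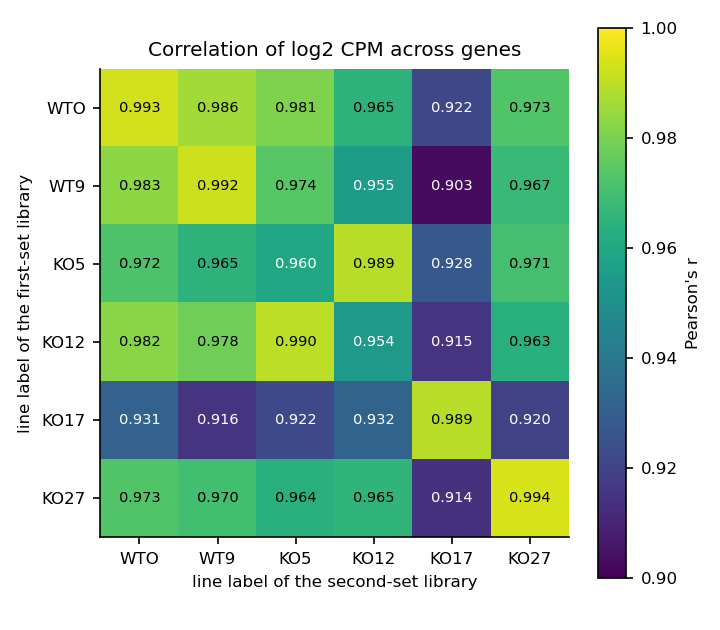
Pearson correlation of log2 CPM across genes (colour scale and printed values) between each library of the first set (vertical axis, by line label) and each of the second set (horizontal axis, by line label). The highest value of every line lies on the diagonal except for KO5 and KO12, whose highest values, 0.9891 and 0.9902, lie with the label of the other line.

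With the libraries of each line summed over both sets, GNG11 and CCR7, which WT lines barely expressed, stood higher in mutant lines. GNG11, a G protein gamma subunit, stood at 0.172 ± 0.0469 CPM in WT (SD, n = 2) and 6.78 ± 2.05 in mutant lines (n = 4), and CCR7, a chemokine receptor, at 0.215 ± 0.0687 and 2.72 ± 0.736. The zinc finger genes ZNF528 and ZNF662 had log2 fold changes of 2.52 ± 0.30 (SE) and 3.77 ± 0.50. The sulfotransferase SULT1C4 had 4.43 ± 0.55. Lower were SLIT2 at -6.94 ± 1.04, EVC at -4.23 ± 0.64, and PDCD5, an apoptosis-related gene, at -0.45 ± 0.068. So was TNFRSF8, which encodes CD30, at -0.65 ± 0.10. By edgeR 0 of 14392 genes passed (smallest adjusted p = 0.314), 1893 had an unadjusted p under 0.05, and DESeq2 called 582, of which 376 were higher. With KO5 and KO12 exchanged, edgeR called 0 genes with 776 at an unadjusted p under 0.05, and DESeq2 called 22. With both lines left out edgeR called 0, with 1614 at an unadjusted p under 0.05, and DESeq2 was not run. The gene values above are as labelled. If the labels were exchanged, the sums of KO5 and KO12 would each mix 2 lines, and the spread between lines would come out too small. The coefficient of variation between lines that edgeR fitted was 29.6% as labelled and 34.7% with the labels exchanged.

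Over both sets 9 lists passed by camera, 6 upward and 3 downward, and 0 with an estimated correlation, where the smallest adjusted p = 0.387 with an estimated correlation. Lower in mutant lines were splicing factors (57 of 70 negative; SRSF3 -0.28 ± 0.071, SE; adjusted p = 1.38e-06), histones (16 of 17; HIST1H2AG -0.21 ± 0.058; adjusted p = 1.38e-06) and ribosomal proteins (42 of 46; adjusted p = 0.001). Higher were the erythroid program (38 of 47 positive; HBZ 1.83 ± 0.40; adjusted p = 0.000631), megakaryocyte markers (8 of 9; ITGB3 2.25 ± 0.36; adjusted p = 0.00334) and p53 targets (16 of 21; BTG2 2.90 ± 0.62, PMAIP1 0.79 ± 0.20; adjusted p = 0.0244). Also higher were interferon genes (21 of 27; TRIM22 2.01 ± 0.44; adjusted p = 0.0252), myeloid markers (10 of 13; CD68 0.58 ± 0.11; adjusted p = 0.0281) and amino acid and ER stress genes (25 of 32; DDIT3 0.49 ± 0.15; adjusted p = 0.0453). By fry megakaryocyte markers (adjusted p = 0.0097) and p53 targets (adjusted p = 0.0467) passed. Adjusted over the list alone, 8 members passed (p53 targets 3, myeloid 2, megakaryocyte 1, cancer-testis 1, glycolysis 1), against 0 over all genes. With KO5 and KO12 exchanged 0 lists passed by fry (smallest adjusted p = 0.615) and 1 member passed adjusted over the list alone. By camera 7 lists then passed, without interferon and p53 genes, and 0 with an estimated correlation (smallest adjusted p = 0.729 with an estimated correlation). With both lines left out 5 passed by camera, and an estimated correlation was not run there. KO17 lay far from the other lines on the first principal component (48.5% of the variance), at 94.3 and 102 against -47.4 to 21.3. Without KO17, 5 lists passed by camera in the first set, 6 in the second set and 7 over both sets. The test was downward for cancer-testis genes (median 0.052, mean 0.28), stem cell and HOX genes (median -0.023, mean 0.35) and glycolysis genes (median -0.046, mean 0.12), and upward for epithelial, fibroblast and endothelial markers (median -0.010, mean 0.43).

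Whether the genotype difference itself differed between the sets was tested with the line as a block. The 5 genes with the smallest p in the negative direction were all small RNA genes, SNORA23 at -1.24 ± 0.18 (log2, SE), SCARNA5 at -1.23 ± 0.18, SCARNA6 at -1.07 ± 0.19, the minor spliceosome RNA gene RNU12 at -1.23 ± 0.23, and SNORA74A at -1.37 ± 0.26. In the positive direction TMPRSS5 had 2.40 ± 0.65, CNIH2 1.91 ± 0.64, TVP23B 0.46 ± 0.16, LINC00308 1.38 ± 0.47 and LRGUK 2.47 ± 0.88. By edgeR 0 of 14098 genes passed, 90 had an unadjusted p under 0.05 and DESeq2 called 4, all negative. Of the lists 0 passed (lowest camera adjusted p = 0.0915, for histones, negative in 17 of 17). The test was upward against a negative median for DNA damage genes (median -0.011, mean 0.0030), p53 targets (median -0.026, mean 0.021), proliferation (median -0.0094, mean -0.0043) and interferon genes (median -0.016, mean -0.038). It was upward for cancer-testis genes with a mean of -0.15 and downward for megakaryocyte markers with a mean of 0.12. With KO5 and KO12 exchanged edgeR called 10 genes, all negative small RNA genes, with SNORA74A at -1.38 ± 0.14 (adjusted p = 1.27e-05) and SNORD17 at -1.09 ± 0.11 (adjusted p = 1.27e-05). Histones were the 1 list that passed (adjusted p = 0.0061, and adjusted p = 0.951 with an estimated correlation). With both lines left out edgeR called 17 genes, 1 positive and 16 negative.

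Between the sets, FOS, EGR1 and the small RNA genes SNORA23, SNORA74A and SCARNA5 rose in the WT lines, and the erythroid genes ALAS2 and HBZ fell, in the second set, which the deposited table names plateau. FOS, an immediate early transcription factor, rose by a log2 fold change of 1.81 ± 0.13 (SE, n = 2 pairs), and EGR1, another, by 1.59 ± 0.16. CD69, a leukocyte activation marker, rose from 15.6 ± 7.83 to 52.1 ± 13.3 CPM (SD). SNORA23, SNORA74A and SCARNA5, small RNAs that guide RNA modification, rose by log2 fold changes of 1.56 ± 0.086 (SE), 1.63 ± 0.10 and 1.57 ± 0.11. A lower recovery of short RNA in the WT libraries of the first set is left open for these genes in the closing section. Also among the largest rises were TUBB4A, a tubulin, at 2.57 ± 0.48, PDE2A, a phosphodiesterase, at 2.01 ± 0.41, TCTEX1D4 at 1.95 ± 0.36 and C19orf35 at 1.68 ± 0.33. The largest falls were in PRG2, an eosinophil granule protein, at -0.87 ± 0.15, SLC7A8, an amino acid transporter, at -0.74 ± 0.12, and FAXDC2 at -0.64 ± 0.11. Falls also included the erythroid membrane protein ERMAP at -0.59 ± 0.084, ALAS2, the first enzyme of erythroid heme synthesis, at -0.57 ± 0.095, and HBZ at -0.54 ± 0.084. LANCL2 and ADI1 fell with -0.51 each, NEFH with -0.50 and PTS with -0.49.

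Of 12997 genes, edgeR called 190 in the WT lines, 167 higher and 23 lower in the second set, and 2193 had an unadjusted p under 0.05. Adjusted p-values were 4.64e-05 for SNORA23, 0.000151 for CD69, 0.00022 for FOS and 0.0364 for TUBB4A, and both lines moved the same way in each. The fit had 1 residual degree of freedom, so that the spread rested on moderation across genes. DESeq2 called 63, of which 62 were among the 190, and without the block edgeR called 0 genes, with 934 at an unadjusted p under 0.05.

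Cholesterol biosynthesis was the most uniform list in the WT lines. All 25 members were higher in the second set and 5 passed, among them INSIG1, a sterol sensor, at 0.47 ± 0.059 (log2, SE) and MSMO1 at 0.40 ± 0.070. Of the 25, 17 passed adjusted over the list alone (camera adjusted p = 8.72e-06, and adjusted p = 0.712 with an estimated correlation). Amino acid and ER stress genes were higher in 30 of 31, and 2 passed, DDIT4, an inhibitor of mTORC1, at 0.73 ± 0.075 and PHGDH, of serine synthesis, at 0.42 ± 0.086. Of the 31, 13 passed adjusted over the list alone (adjusted p = 8.72e-06, and adjusted p = 0.712 with an estimated correlation). Myeloid markers were higher in 9 of 10, 0 passed over all genes and 3 adjusted over the list alone (CD68 0.40 ± 0.089, CD33 0.36 ± 0.088; adjusted p = 0.00295, and adjusted p = 0.712 with an estimated correlation). The erythroid program was lower in 32 of 45 members and 5 fell, among them HBZ, ALAS2 and KEL at -0.43 ± 0.075. Of the 45, 9 passed adjusted over the list alone (adjusted p = 0.000107, and adjusted p = 0.712 with an estimated correlation). Splicing factors were lower in 53 of 70, although the 1 member that passed, MBNL2, rose with 0.38 ± 0.079 (adjusted p = 0.0261, and adjusted p = 0.712 with an estimated correlation).

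Single members of other lists passed in the WT lines. PLK3 of the p53 list rose with 0.57 ± 0.11 (log2, SE), GP6 of the megakaryocyte list with 0.63 ± 0.12, and PRF1 of the lymphoid list with 0.91 ± 0.17. Others that rose were FN1 of the fibroblast list with 0.32 ± 0.062, GATA2 of the stem cell list with 0.28 ± 0.057, and SLC2A3 and VEGFA of the glycolysis and hypoxia list with 0.40 ± 0.055 and 0.37 ± 0.067. The cyclin CCNE2 fell with -0.45 ± 0.081. Camera adjusted p-values of the other 13 lists ran from 0.0747 for lymphoid markers to 0.823, and by fry 0 lists passed. DNA methylation machinery had a median of 0.018 and a mean of 0.0081 with a downward test. Adjusted over the list alone, 62 members of all lists passed.

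In the mutant lines, with the libraries paired as labelled, no single gene passed between the sets, and 7 lists passed by camera. The smallest adjusted p = 0.862 with an estimated correlation, so that 0 passed there. The 5 lists that passed in WT lines were among the 7, in the same direction, and histones and ribosomal proteins were added, which had adjusted p-values of 0.205 and 0.287 in WT lines. The difference between genotypes was tested above, where 0 lists passed. Erythroid genes were lower in the second set in 44 of 46 members, with the transcription factors KLF1 at -0.32 ± 0.10 (log2, SE) and GATA1 at -0.18 ± 0.065 (camera adjusted p = 6.05e-05, and adjusted p = 0.862 with an estimated correlation). Splicing factors were lower in 60 of 70, with SF3A1 at -0.21 ± 0.076 (adjusted p = 6.87e-06, and adjusted p = 0.862 with an estimated correlation). Histones were lower in 17 of 17 (adjusted p = 0.000177, and adjusted p = 0.862 with an estimated correlation) and ribosomal proteins in 37 of 46, with RPS16 at -0.34 ± 0.088 (adjusted p = 0.0421, and adjusted p = 0.907 with an estimated correlation). Cholesterol genes were higher in 21 of 25, with INSIG1 at 0.60 ± 0.20 (adjusted p = 0.00321, and adjusted p = 0.862 with an estimated correlation). Amino acid and ER stress genes were higher in 26 of 31, with ASNS at 0.30 ± 0.11 (adjusted p = 0.000347, and adjusted p = 0.862 with an estimated correlation), and myeloid markers in 11 of 12 (adjusted p = 0.02, and adjusted p = 0.862 with an estimated correlation). The other 11 lists had adjusted p-values from 0.0523 for proliferation to 0.99. Adjusted over the list alone 0 members passed, and by fry 0 lists passed. Medians and tests differed in sign for DNA damage genes (median 0.0013, mean -0.0071, downward test) and epithelial, fibroblast and endothelial markers (median 0.0060, mean 0.031, downward test). The mean was positive with a downward test for DNA methylation machinery (0.028), stem cell genes (0.019) and glycolysis genes (0.0077). Without KO5 the erythroid list had an adjusted p of 0.933 and the opposite direction, against 9e-10 without KO12. Without KO12 the ribosomal list had 0.259 and the opposite direction, against 0.00457 without KO5, and 3 lists passed instead of 7. If the labels of KO5 and KO12 were exchanged, leaving out 1 of them keeps a pair of 2 different lines. These values would then hold a difference between lines. With the labels exchanged 44 of 46 erythroid genes were lower (camera adjusted p = 6.59e-11, and adjusted p = 0.599 with an estimated correlation).

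**Figure D3:**
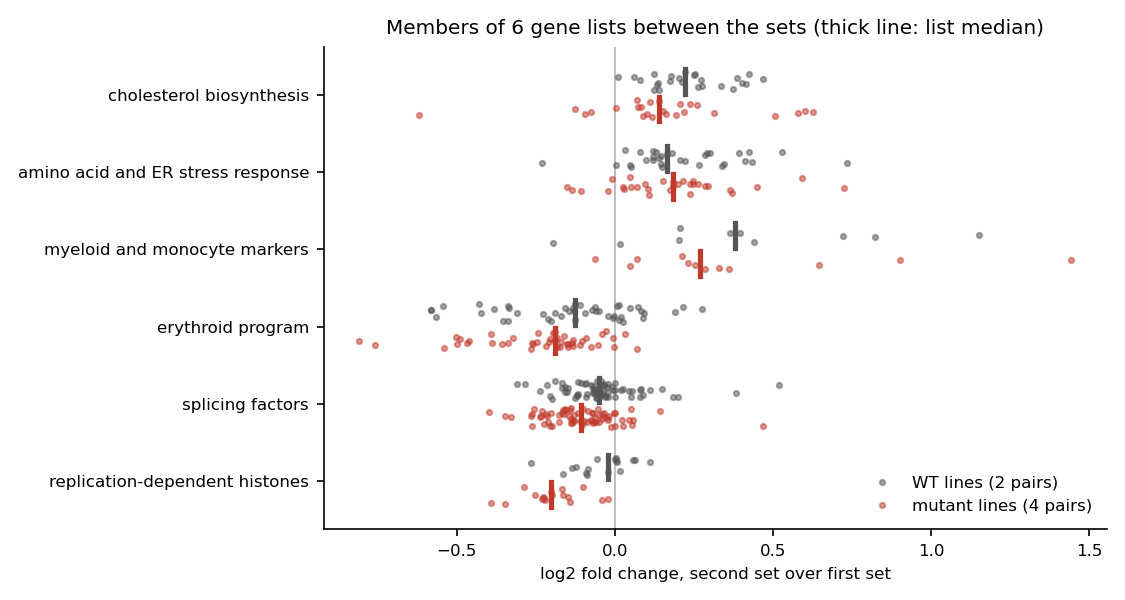
Log2 fold change of the second over the first set (horizontal axis) for the members of 6 gene lists (vertical axis); points are genes, grey for 2 WT pairs and red for 4 mutant pairs as labelled, and thick lines are list medians. All 25 cholesterol genes lay above 0 in WT lines, and 44 of 46 erythroid genes lay below 0 in mutant lines.

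The genes with the smallest p in mutant lines were SCARNA10 at 0.44 ± 0.095 (log2, SE), TM6SF1 at 0.67 ± 0.15, the ubiquitin ligase PELI1 at 0.49 ± 0.11, CCNG1, a cyclin induced by p53, at 0.35 ± 0.082, and SOCS3, an inhibitor of cytokine signalling, at 0.39 ± 0.098. In the negative direction they were the neuropeptide precursor VGF at -0.96 ± 0.19, CCDC86 at -0.47 ± 0.11, CLN6 at -0.39 ± 0.092, C1orf216 at -0.37 ± 0.087 and ARMC5 at -0.40 ± 0.097. By edgeR 0 of 13067 genes passed (smallest adjusted p = 0.932), 529 had an unadjusted p under 0.05, and DESeq2 called 0. With KO5 and KO12 exchanged in the second set edgeR called 394 genes, 244 higher and 150 lower, and DESeq2 193; with both lines left out edgeR called 6.

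Splicing was compared between a WT pool and a mutant pool in each set, with no replicates, so that no spread between lines stands behind an event. The tables listed 240 events in the first set. These were 117 skipped exons (SE), 49 alternative 3' splice sites (A3SS), 36 alternative 5' splice sites (A5SS), 19 mutually exclusive exons (MXE) and 19 retained introns (RI). In the second set they listed 81 events, 31, 10, 12, 17 and 11 of these types. Inclusion was higher in the mutant pool for 50 of 117 skipped exons of the first set (42.7%, exact 95% interval 33.6% to 52.2%; exact binomial p = 0.139) and for 19 of 31 of the second set (61.3%, 42.2% to 78.2%; exact binomial p = 0.281), each with an adjusted p of 0.947 over the 10 tables. At a Bayes factor of at least 100, inclusion was higher in the mutant pool for 6 of 6 skipped exons of the second set (100%, exact binomial p = 0.0312, not adjusted). These 6 events lay in 5 genes. In the first set the share at this Bayes factor was 36 of 81 (44.4%, exact binomial p = 0.374). For the second set the exact binomial p was 0.167 at a difference of at least 0.3 and 0.362 with at least 50 reads in each pool. These p-values treat events as independent and hold no spread between libraries. Of the first set events 63 (26.2%) had 0 reads of an isoform in 1 pool and at least 20 in the other, 61 of them in the WT pool; in the second set there were 0 of 81. Without these 63, 177 events remained in the first set.

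**Figure D4:**
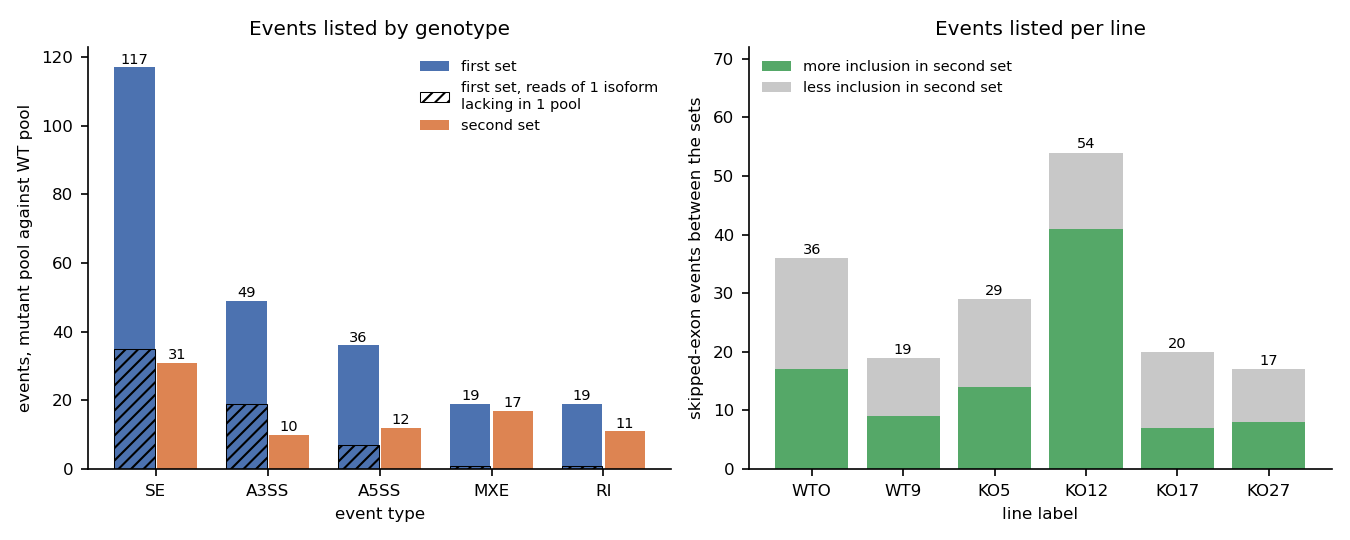
Number of listed splicing events (vertical axes) by event type and set between the mutant and WT pools (left) and of skipped-exon events between the sets by line label (right). Hatching marks events of the first set with 0 reads of an isoform in 1 pool, 63 in all, and KO12 has the most events of a line, 54.

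The largest differences of the first set were in exons of CCDC14 and ENSG00000291147 and in a 3' splice site of GATAD2A. An exon of CCDC14, a centriolar satellite protein, on chromosome 3 (hg19, 123674690 to 123674812) was included at a fraction of 0.05 in the WT pool (credible interval 0.02 to 0.12) and 0.94 in the mutant pool (0.87 to 0.99). A noncoding exon of ENSG00000291147 on chromosome 2 went from 0.04 to 0.93. At 3' splice sites, GATAD2A, a subunit of the NuRD complex, went from 0.95 to 0.06 and CLK2, a kinase of splicing factors, from 0.08 to 0.75. At 5' splice sites, the tight junction gene TJP1 went from 0.13 to 0.95 and RAN, the nuclear transport GTPase, from 0.86 to 0.09. Exclusive exons of NBPF14 (0.44 to 0.96) and of CPEB4, a translation regulator (0.45 to 0.96), and retained introns of OGFOD2 (0.87 to 0.26) and CCDC14 (0.64 to 0.08) completed the largest of each type; paralogs may share reads of NBPF14. The WT pool had 0 reads unique to the shorter isoform for TJP1, RAN and the introns of OGFOD2 and CCDC14, and 0 unique to the longer isoform for ENSG00000291147 and CLK2. It had 4 reads unique to the longer isoform for the CCDC14 exon, against 148 in the mutant pool. For GATAD2A it had 1 read unique to the shorter isoform, against 469.

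In the second set the largest differences were in skipped exons of ADPRH (0.16 in WT to 0.72 in mutant) and HAPLN3 (0.15 to 0.67), 3' splice sites of RBM39, a splicing factor (0.75 to 0.23), and PNPLA6 (0.17 to 0.66). They were also in 5' splice sites of IQCH-AS1 (0.40 to 0.87) and ZNF211 (0.42 to 0.87), and exclusive exons of RAD18, a ubiquitin ligase of DNA damage tolerance (0.80 to 0.20), and YAF2 (0.73 to 0.20). Introns with the largest differences were those of DUS1L (0.65 to 0.08) and DNHD1 (0.76 to 0.21). For ADPRH, HAPLN3, RBM39, PNPLA6, IQCH-AS1, ZNF211, DUS1L and DNHD1, 1 of the pools had 0 reads unique to an isoform. Several fractions rested on few reads that matched an isoform. In the WT and mutant pools these were 13 and 12 for RBM39, 8 and 12 for PNPLA6, and 10 and 16 for RAD18. For DUS1L they were 129 and 126. The credible interval of RBM39 in the WT pool ran from 0.42 to 0.98. Both sets listed 4 identical events. An exon in the untranslated region of CREBZF, a transcription factor, on chromosome 11 (85372681 to 85372793) was less included in the mutant pool, from 0.77 to 0.23 in the first set and 0.51 to 0.18 in the second set. A 3' splice site of TUBA1A, a tubulin whose reads paralogs may share, went from 0.23 to 0.82 and from 0.32 to 0.70, and an exclusive exon of ABCD4, a vitamin B12 transporter, from 0.68 to 0.39 and from 0.69 to 0.38. A retained intron of GRTP1 went up from 0.07 to 0.43 in the first set and down from 0.39 to 0.05 in the second set. The tables list only events past their filter, so that an event absent from a table is not shown to be unchanged.

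Between the sets, skipped-exon events were counted per line. The tables listed 36 events for WTO, 19 for WT9, 29 for KO5, 54 for KO12, 20 for KO17 and 17 for KO27. The mean was 27.5 ± 12.02 (SD, n = 2) in WT and 30 ± 16.79 (n = 4) in mutant lines, a difference smaller than the spread (exact permutation p = 0.933; the smallest p that 15 arrangements allow is 0.0667). The sign of the difference rested on single lines, as the mutant mean was lower by -6.0 without WT9 and by -5.5 without KO12. Inclusion was higher in the second set for 41 of 54 events of KO12 (75.9%), and for 17 of 36 in WTO, 9 of 19 in WT9, 14 of 29 in KO5, 7 of 20 in KO17 and 8 of 17 in KO27. The share was 47.3% ± 0.1 in WT and 51.6% ± 17.3 in mutant lines (exact permutation p = 0.8), and without KO12 the mutant mean was lower by -3.85. The labels of KO5 and KO12 that the expression profiles question also name these tables.

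The largest changes within lines were in TACC1 for WTO (0.20 in the first to 0.84 in the second set), ATG12 for WT9 (0.19 to 0.73), FGF13 for KO5 (0.71 to 0.10), ZNF37A for KO12 (0.25 to 0.83), ALAS1 for KO17 (0.25 to 0.79) and CERT1 for KO27 (0.68 to 0.08), genes chosen after their values were seen. Of 171 distinct events 167 were listed for a single line, 4 for 2 lines and 0 for 3 or more. The 4 were exons of AGAP1, up in WTO and KO12, KLHL8, from 0.79 to 0.47 in WTO and from 0.38 to 0.81 in KO12, LRRFIP2, from 0.67 to 0.42 in KO5 and from 0.42 to 0.68 in KO12, and FGF13, from 0.71 to 0.10 in KO5 and from 0.22 to 0.69 in KO12. In LRRFIP2 and FGF13 the changes of KO5 and KO12 thus ran in opposite directions.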

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

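Every test of an explanation in this part, and the exchange of the labels KO5 and KO12, was chosen only after the result it measures had been seen. Among 56 groups of values from the 4 mutant lines, 4 had 1 value far from the other 3. The 56 covered gene levels, library measures and splicing counts per line, and the 4 were all gene levels. Chance gives this in about 1 in 20 groups of normally distributed values. A group with counts in 1 library only is always flagged. In the second set, the ITGA4 level of 0.0627 CPM in KO12 stood apart because the other 3 libraries had 0 counts, and it rests on 1 count. In the first set, the SEMA3D level of 0.0920 CPM in KO17 likewise rests on 1 count. SLIT2 stood at 0.749 CPM in KO27 of the second set, above the other mutant libraries and far below the WT mean of 25.9. SCARNA5 stood at 55.2 CPM in KO17 of the first set, above the other 3 mutant libraries.

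A difference between groups was seen in 10 genes whose genotype effect differed between the sets when the labels of KO5 and KO12 were exchanged in the second set. All 10 were small RNA genes, SNORA74A, SNORA23, SNORA74B, SNORA64, SNORD17, SNORD22, SCARNA1, SCARNA5, SCARNA6 and RNU12. As labelled, edgeR called 0 genes with 90 at an unadjusted p under 0.05, and DESeq2 called 4. A retained intron of GRTP1 changed by 0.36 in the first set and by -0.34 in the second set; this difference between the sets was not tested.

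The first pattern is that the second set libraries of KO5 and KO12 resemble the first set library of the other line. Changes of these lines that were unrelated to each other are argued against, since the second set library of each was closest to the other line. As deviations from the group mean across genes, the first and second set libraries correlated at -0.266 for KO5 and -0.312 for KO12 as labelled. With the labels exchanged they correlated at 0.797 and 0.848, against 0.921 for KO17 and 0.798 for KO27. Mirrored changes of the lines cannot be told apart from an exchange of the labels. The set change of KO5 correlated with that of KO12 at -0.708 across genes, while the other 14 pairs of lines lay between -0.0286 and 0.249, but this value follows from the resemblance itself. An exchange of the labels in 1 of the sets stays open and may explain the pattern. The lower of the correlations across exchanged labels was 0.9891, near the lowest own-label correlation of the other 4 lines, 0.9894, and above the 0.9541 of KO12 with its own label. The tables do not show which set would carry the exchange, and a biological cause of such a mirrored change was not tested.

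The second pattern is that small RNA genes were lower in the WT libraries of the first set, relative to the mutant libraries and to the second set. The values below rest on the exchanged labels of KO5 and KO12; as labelled, edgeR called 0 genes for this difference, with 90 at an unadjusted p under 0.05, and DESeq2 called 4. A lower transcript level of their host genes is argued against. The median difference of differences (log2) was 0.003 in 6 host genes (range -0.154 to 0.099), against -1.076 in the 10 small RNA genes. Counts measure transcript level, so that lower transcription of the host genes was not tested. A lower recovery of short RNA in those libraries stays open, with values on both sides. Of 220 small RNA genes 76.4% lay below 0, against 52.1% of all genes, which a loss of the class would give. Against a loss that grows with shortness, longer small RNAs lay lower (rho = -0.265 in 195 genes), a trend across genes of the same libraries that holds no spread between libraries. Growth state, which differs between the sets by the name of the tables, and genotype stay open as biological explanations and were not tested.

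The third pattern is that the first set tables list 240 splicing events between the pools and that the second set lists 81. Reads of an isoform missing from the WT pool of the first set may explain part of it. In the first set 63 events (26.2%) had 0 reads of an isoform in 1 pool and at least 20 in the other, 61 of them in the WT pool, against 0 of 81 in the second set and 0 of 175 in the lines. Without them 177 events remained. That count keeps events with few reads of an isoform in the WT pool instead of 0, such as GATAD2A with 1 against 469 in the mutant pool. It therefore does not show how many events the first set would list without missing reads. Whether the genotype difference was present in both sets cannot be told apart from other causes: of 71 first set events at the largest Bayes factor the second set tables list 1, and an event that a table leaves out has no value there. Of 17 skipped exons with a difference of at least 0.6 in the first set, 0 are in the table of any line, which leaves a difference between the sets within lines open for the same reason.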

How the results depend on the processing

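Of the alternatives in this part, the exact test, the exchange of KO5 and KO12 and leaving both out were chosen only after the data had been seen. Over 330 results of named genes, 2987 of 3206 values under an alternative kept their direction and their side of the threshold, 148 kept the direction and newly passed, 51 kept it and no longer passed, and 20 changed sign. Over 33 list results, 180 of 264 values did not change side, 81 no longer passed and 3 changed direction.

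DESeq2 in place of edgeR called 10 genes in the first set, 17 in the second, 582 over both sets and 4 for the difference between the sets, against 0 by edgeR in each, and 63 in the WT lines against 190. With KO5 and KO12 exchanged, DESeq2 called 22 genes over both sets in place of 582. The exact test without a filter called 5 genes in each set. In the WT lines DESeq2 size factors gave 357 genes and no filter 422, both with all 190; without the block edgeR called 0, with 934 at an unadjusted p under 0.05. The cause was not tested. Exchanging KO5 and KO12 gave 10 genes for the difference between the sets and 394 in mutant lines; leaving both out gave 17 and 6, with fewer lines.

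Leaving out single lines, edgeR called 0 to 1 genes over both sets (1 without KO17) and 0 to 1 for the difference between the sets (1 without KO12). Lists past the threshold were 3 to 8 in the first set (3 without KO5 and without WT9), 2 to 9 in the second (2 without KO12, 3 without WT9) and 3 to 9 in mutant lines (3 without KO12), against 6, 6 and 7. Without a filter 3 lists passed in the second set. Without KO5 and KO12 5 passed over both sets and 4 in mutant lines. With an estimated correlation 0 passed in each comparison. In the first set the estimates for the 6 lists that passed ran from 0.283 for the erythroid program to 0.745 for ribosomal proteins, against the assumed 0.01. Over both sets megakaryocyte markers also lost their pass, at an estimate of -0.0604. A higher correlation thus does not account for every list, and other causes were not tested.

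DNMT3A, whose differences were smaller than their SE, ran without single lines from -0.21 to 0.086 in the first set, -0.073 to 0.13 in the second, -0.15 to 0.045 over both and -0.045 to 0.25 for their difference (log2). Values of the other sign came without KO12 in the first set (0.086), without WTO (-0.015), KO5 (-0.021) or KO27 (-0.073) in the second, without KO12 (0.045) or KO17 (0.027) over both, and without KO12 for the difference (-0.045). With KO5 and KO12 left out DNMT3A was 0.064 over both sets, -0.16 for the difference and -0.11 in mutant lines, GFI1B 0.080 and FN1 -0.0031 in mutant lines.

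Other genes that changed sign were MAEL in the second set (-8.82 to 0.56, the latter without WT9), SNORD17 (-0.30 to 0.18, the latter without WTO) and RPS16 for the difference (-0.41 to 0.018, the latter without WTO). In mutant lines the sign changed without KO5 for GFI1B (-0.22 to 0.064), PRF1 (-0.0026 to 0.65), HBZ (-1.61 to 0.048), SLC4A1 (-1.39 to 0.30) and GYPB (-1.16 to 0.33). The erythroid list had adjusted p-values of 9e-10 to 0.933 in mutant lines (0.933 and upward without KO5). Ribosomal proteins had 0.00457 to 0.259 (0.259 and upward without KO12) and 0.763, upward, with KO5 and KO12 left out. With the labels exchanged the camera adjusted p was 6.59e-11 for the erythroid and 0.0239 for the ribosomal list, both downward. Neither passed with an estimated correlation. Where the sets are paired, fits without KO5 or KO12 alone keep a pair that may join 2 different lines. A sign change there cannot be told apart from an effect of the labels.

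At a Bayes factor of at least 100, 158 and 16 splicing events remained. Inclusion was then higher in the mutant pool in 100% of the skipped exons of the second set (6 of 6, in 5 genes, exact binomial p = 0.0312). In the first set it was higher in 44.4% (36 of 81, exact binomial p = 0.374). Both p-values take events as independent. Mutant minus WT mean events per line ran from -6.0 (without WT9) to 11, with -5.5 without KO12 and -9.0 without KO5 and KO12. For the share with higher inclusion in the second set it ran from -3.85 (without KO12) to 9.79 percentage points, with -6.27 without KO5 and KO12 and -16.7 at a Bayes factor of at least 100. The cause was not tested.

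The WT comparison between the sets could not be run without a line, which leaves 0 residual degrees of freedom, and alternatives for FPKM values were not run because the counts were analysed. With 2 WT lines, each fit without a WT line assumes that the lone line varies like the mutant lines.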

Other observations

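Every test in this part was chosen only after the values had been seen, including the exchange of KO5 and KO12 and the counts of other splits. With those labels exchanged in the second set, edgeR called 394 genes between the sets in mutant lines. Among the falls were the neurofilament gene NEFH at -1.01 ± 0.14 (log2, SE), HBZ at -0.88 ± 0.11, VGF at -0.86 ± 0.14, the band 3 anion exchanger SLC4A1 at -0.65 ± 0.16 and RELN at -0.63 ± 0.088. Among the rises were the nerve growth factor receptor NGFR at 1.16 ± 0.21, TMEM108 at 1.75 ± 0.37 and MIR3189 at 1.10 ± 0.23. The reads at MIR3189 may come from a longer transcript, which was not tested. Of the erythroid list 11 members fell and 28 passed adjusted over the list alone (camera adjusted p = 6.59e-11, and adjusted p = 0.599 with an estimated correlation). Of the cholesterol list 5 rose, among them MSMO1 at 0.57 (adjusted p = 0.00299, and adjusted p = 0.603 with an estimated correlation). Of the amino acid and ER stress list 5 rose, among them DDIT4 at 0.75 (adjusted p = 0.00125, and adjusted p = 0.603 with an estimated correlation). Of the splicing list 6 fell, HNRNPM at -0.32 among them, and MBNL2 rose with 0.49 (adjusted p = 2.86e-07, and adjusted p = 0.599 with an estimated correlation).

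The genes called in the WT lines overlapped with these. Of genes tested in both comparisons, 63 rose in both, where 3.13 were expected by chance, and 15 fell in both, where 0.273 were expected. Of the 190 genes called in WT lines 181 had the same sign in mutant lines. Genes are not independent replicates, so that these numbers describe the overlap and carry no test.

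Other splits of the 8 mutant libraries into groups of 4 were fitted with the same block, 32 of 35, and 3 could not be fitted. As labelled, the real split gave 0 genes, a number that all 32 splits reach by construction, so that this count tests nothing. It gave 7 lists, and 18 splits gave as many (highest other 10). Splits that part only 2 of the pairs come in twos with the same fit, so that the 32 splits are not 32 separate fits. Among the 8 splits that part all pairs, 6 gave as many, the real one included (highest other 8). Chance cannot be excluded for the lists. The 2 splits with 2132 genes are the same fit. Each parts the pairs of KO5 and KO12 alone and joins the first set library of KO5 with the second set library of KO12, which points to a structure of the samples. With the labels exchanged, 3 splits gave at least the 394 genes of the real split (highest other 438). The other 2 of these are the same fit. They part only 2 of the pairs, each into its first and second set library, so that they repeat the real contrast in part and say nothing about chance. Among the 8 splits that part all pairs, 1, the real one, did, with 235 genes as the highest other. For the lists 1 split, the real one, gave 10 (highest other 9). The 8 splits that part all pairs are too few for a share under 0.05 in either count.

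KO17 stood apart from all other lines in expression. On the first principal component, with 48.5% of the variance, its libraries lay at 94.3 and 102, and those of the other lines between -47.4 and 21.3. An exon of KAT6A, an acetyltransferase gene, had 44 inclusion reads in the KO27 library of the first set and 10 in the mutant pool of the same set, with fractions of 0.59 and 0.05. At the other skipped exons listed for both a line and its pool, the line did not exceed the pool in reads. How the pools were made from the lines is not given in the sources used here.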
